A study of Oryza sativa with 6 samples.

How the data were processed

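Gene expression was measured in root tips of rice (Oryza sativa) seedlings of 2 varieties with 2-colour Agilent arrays. IR64 is a shallow-rooting lowland variety, and Dro1-NIL is a near-isogenic line that carries the Kinandang Patong allele of DRO1 (DEEPER ROOTING 1), a gene of root growth angle, in the IR64 background. Per the labels' protocols, 5-day-old seedlings were moved to nutrient solution with 10 µM of the synthetic auxin 2,4-D, and tips of 2 to 3 mm from 15 seedlings per repeat were taken before the transfer (0 h) and after 3 h. Each of the 6 arrays (3 per variety, labelled as biological repeats) held the 3 h RNA in Cy5 and the 0 h RNA of the same variety in Cy3, per the labels' protocols. No array had the dyes swapped, and no seedlings kept for 3 h without auxin were analysed here, so the ratio of 3 h to 0 h holds the effects of auxin, of transfer and of elapsed time, together with any bias between the dyes.

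The authors' spot intensity values (mean signal and median local background of each dye) were deposited as the scanner software wrote them, Agilent Feature Extraction 10.5.1.1 per the submitters' processing notes. Feature Extraction's processed intensity values, background-subtracted, detrended and dye-normalized per the file headers, and its log10 ratio of Cy5 over Cy3 were deposited in the same files and served as alternatives. The authors' deposited value table held log2 ratios that equalled the log2 of Feature Extraction's dye-normalized Cy5 over Cy3 signals, with differences of at most 1.46e-05. Its array medians lay between -0.19 and 0.02, so it was not centred, and its direction was 3 h over 0 h. Background and scanner settings beyond the header columns are not given in the sources used here.

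Each array had 45151 spots, among them 1417 control spots. The median mean signal was 315 to 369 in Cy3 and 671 to 744 in Cy5, against median local backgrounds of 24 to 28 and 62.5 to 64. Between 70.2% and 75.6% of the probes were well above background per array and dye, no spot was saturated, and 18 to 71 spots per array had an outlier mark and were left out. With 3 arrays per variety, the number of arrays limits the precision of every value below.

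Log2 ratios were computed with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading tables and statmod 1.5.0 for the random block. Background was corrected with normexp (offset 50) and each array was normalized by loess, with control spots at weight 0 and then left out. Spots of one probe were averaged. Of 42426 probes, 41908 carried a rice locus identifier in the array files. A probe was tested where it was well above background on all 3 arrays of at least 1 variety and dye, which 31567 probes were. Each gene was represented by its brightest tested probe, giving 21911 genes, of which 21797 had a locus identifier and 113 were microRNA probes, and 6219 had over 1 tested probe. Genes are named by locus and by the array's own description, which can be old, since no locus identifier matched the gene table used here. DRO1, qSOR1 and LAZY1 were named from general knowledge of their loci, and CRL1 was not analysed here.

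The auxin response of each variety and their difference came from 1 limma fit of the 6 log2 ratios with a coefficient per variety. The varieties were compared at 0 h in the Cy3 channel and at 3 h in the Cy5 channel after Aquantile scaling between arrays, so that each comparison stayed within 1 dye. Empirical Bayes variances followed a trend on intensity, and Benjamini-Hochberg adjusted p-values under 0.05 over all genes were called. Errors given with ± are standard deviations over the 3 arrays of a variety (SD), or standard errors of limma's contrast where marked SE. A probe that was not well above background on any array of a group has only a bound there, and the fold is then given as at least the bright group's mean over the dim group's bound. A total of 30 gene lists, chosen by words in the gene descriptions or by locus, were tested with camera (preset correlation 0.01, lists of 5 or more measured genes), with camera with an estimated correlation and fry as alternatives. The variance trend of camera was left out for ratios. Words catch some wrong members: the ethylene response factor list holds translation release factor and methionine synthase genes, and the photosynthesis list is led by plastocyanin-like domain proteins.

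The design, tests, gene lists and alternatives, apart from the alternatives given at the end of this section, were fixed before the data were examined. Genes were named by a rule fixed then: the 10 highest and 10 lowest auxin responses called in both varieties with all 6 arrays on one side, up to 3 members per list with the smallest adjusted p, all measured Aux/IAA genes, and up to 8 genes per direction for each comparison of the varieties. Where fewer than 6 genes were called for a comparison, the 6 with the smallest p were named as not called. Genes without a descriptive name were passed over, except DRO1, qSOR1, LAZY1 and the Aux/IAA genes.

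The fits were tested on simulated data of 21911 genes each, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. At 2-fold, 100% of the changed genes were recovered for the IR64 response, 86.6% for the Dro1-NIL response, 74.6% for the difference of the responses, 89.6% at 0 h and 82.1% at 3 h. At 1.5-fold these shares were 74.6%, 70.1%, 64.2%, 68.7% and 62.7%, and at 4-fold 93.9%, 95.5%, 97.0%, 100% and 98.5%, with 7 to 10 false calls per simulation. The simulated noise was independent between genes and arrays, with 1 spread per gene for all arrays. The real arrays were less even, with array weights of 0.20 for IR64 replicate 1 and 4.41 for IR64 replicate 2. Few genes were changed in each simulation, while 71.4% of genes were called for the real IR64 response and 72.9% for the real Dro1-NIL response. The Benjamini-Hochberg adjustment depends on that share. For both reasons the recovered shares may not hold for the real data, and they do not describe the calls of the auxin responses. This testing was done after the first calls had been seen, and it exposed an error: the variance trend of the ratio fit had been placed on the mean log ratio in place of intensity. Correcting it changed the calls from 15803 to 15638 in IR64, from 16168 to 15969 in Dro1-NIL and from 3 to 0 for the difference between the responses. Among 20 simulated lists of 30 genes, camera called the 1 list shifted by 0.5 log2 and 0 of the others. These genes were drawn independently, so the run could not test the preset correlation for genes that vary together. It covered the mean response of both varieties only, and no smaller shift.

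Same-numbered arrays of the varieties lay on the same slide by the slide numbers that the deposited files carry, so each of the 3 slides held both groups. The labels do not state this, and the slide blocks and within-slide values rest on it. Alternatives were the slide as a fixed or random block, no background correction or another normexp offset, Feature Extraction's own values, the deposited table, median centring, no or a stricter filter on dim probes, the mean over probes, variances without trend, array weights, a fit of both channels together, and leaving out each array in turn. Added after the data had been seen were the variance trend as first run, the values of lists, of the overlap and of DRO1 without each array, the fixed block and median centring for lists, and the settings of DRO1 other than Feature Extraction's values and the fixed block. The closing section gives their effect.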

Results

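Expression was compared in rice root tips before and 3 h after exposure to 10 µM 2,4-D, in IR64 and in Dro1-NIL, with 3 arrays per variety. Across 21911 genes, the log2 ratios of 3 h to 0 h correlated at 0.967 to 0.976 between arrays of Dro1-NIL. Between arrays of IR64 they correlated at 0.90 to 0.976, where IR64 replicate 1 gave the lower values of 0.90 and 0.926. Across the varieties the correlations were 0.902 to 0.970. IR64 replicate 1 correlated with Dro1-NIL replicates 1, 2 and 3 at 0.939, 0.962 and 0.942, so this array did not group with its own variety. Genes are not independent replicates, and these correlations describe the arrays only.

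The first question was which genes change in the root tip within 3 h of auxin. The highest named responses in both varieties were those of aldolase C-1 (Os08g0120600), a glycolytic enzyme, with log2 ratios of 7.48 ± 0.32 in IR64 and 7.44 ± 0.40 in Dro1-NIL (SD, n = 3 each). Non-symbiotic hemoglobin 2 (Os03g0226200, 6.83 ± 0.06 and 6.81 ± 0.03) and hemoglobin 1 (Os03g0233900, 6.45 ± 0.13 and 6.54 ± 0.04), which bind oxygen and nitric oxide, rose nearly as far. A family 1 glycoside hydrolase (Os09g0511600, 6.55 ± 0.30 and 6.73 ± 0.29) and an AUX/IAA family gene (Os06g0166500, 6.91 ± 0.45 and 6.26 ± 0.32) were in the same range. So was the glutathione S-transferase GST 30 (Os10g0530900, 6.40 ± 0.19 and 6.07 ± 0.12). The 10 highest named genes also held a GH3 homologue (Os05g0500900, 5.96 ± 0.15 and 6.02 ± 0.13) and a ferredoxin-nitrite reductase of nitrate assimilation (Os01g0357100, 5.55 ± 0.10 and 5.54 ± 0.08). The remaining pair were the late embryogenesis abundant proteins Os05g0542500 (6.08 ± 0.14 and 5.83 ± 0.11) and Os01g0314800 (5.66 ± 0.30 and 5.42 ± 0.14).

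The lowest named responses were those of a NAM/CUC2-like transcription factor gene (Os04g0515900) and a DNA-binding protein gene (Os03g0171300, -5.30 ± 0.20 in IR64 and -5.27 ± 0.21 in Dro1-NIL). The NAM/CUC2-like gene was not well above background at 3 h and was at least 37.2-fold lower than at 0 h in IR64 and at least 35.2-fold lower in Dro1-NIL. The sodium transporter gene Os06g0701700 was at least 29.9-fold and at least 27.3-fold lower. The root-specific protein RCc2 (Os10g0551800, -4.96 ± 0.48 and -5.19 ± 0.40), a GASA5-like gene (Os09g0414900, -4.69 ± 0.35 and -4.98 ± 0.25) and a protein kinase gene (Os01g0935800, -4.87 ± 0.29 and -4.73 ± 0.15) fell too. Remorin (Os03g0111200, -4.66 ± 0.23 and -4.65 ± 0.15), a xyloglucan endotransglycosylase (Os06g0696600, -4.76 ± 0.73 and -4.31 ± 0.15), a DREPP membrane polypeptide (Os02g0285300, -4.33 ± 0.10 and -4.48 ± 0.14) and an RNA-binding protein gene (Os06g0220600, -4.27 ± 0.20 and -4.19 ± 0.21) completed the 10. All genes of both sets were called in both varieties, with limma adjusted p between 8.75e-09 and 1.07e-05.

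Over all genes, limma called 15638 in IR64 (7985 higher and 7653 lower at 3 h) and 15969 in Dro1-NIL (8168 higher and 7801 lower). Of these, 3716 and 3804 changed at least 2-fold. Higher calls made up 51.1% in both varieties. With median centring in place of loess they made up 70.6% in IR64 and 69.9% in Dro1-NIL, and the median of all genes moved to 0.27 in each. Directions of small responses are therefore relative to the loess scale.

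Aux/IAA genes, which encode repressors of auxin signalling, were mostly higher after auxin. Of 29 measured members, 24 rose and 3 fell in IR64, and 23 rose and 3 fell in Dro1-NIL (24 and 3, and 25 and 3, when adjusted over the list alone). Besides Os06g0166500, members with high responses were Os02g0805100 (4.59 ± 0.43 in IR64 and 4.80 ± 0.20 in Dro1-NIL), Os05g0559400 (2.94 ± 0.31 and 3.11 ± 0.15) and Os05g0186900 (2.87 ± 0.34 and 2.94 ± 0.26). The 3 members that fell were Os06g0355300 (-0.65 ± 0.06 and -0.53 ± 0.08), Os08g0109400 (-0.50 ± 0.13 and -0.46 ± 0.05) and Os01g0927600 (-0.26 ± 0.13 and -0.26 ± 0.05), the last of which was higher at 3 h with median centring (0.13 and 0.15). Members were matched by description, and whether each encodes a repressor, Os01g0927600 among them, was not analysed here. With Feature Extraction's values the fall was larger for Os06g0355300 (-1.07 and -0.89) and Os08g0109400 (-1.06 and -1.10). The list's median log2 ratio was 0.92 in IR64 and 1.02 in Dro1-NIL, and camera placed it above other genes in both (adjusted p = 2.93e-05 each). With an estimated correlation the adjusted p was 0.690 and 0.668.

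Other auxin families went in both directions. Among 10 GH3 genes, which encode enzymes that conjugate auxin, 5 rose and 4 fell in IR64 and 5 rose and 3 fell in Dro1-NIL, with 5 and 4 in each when adjusted over the list alone. Os05g0500900 and Os01g0764800 (3.52 ± 0.47 and 3.61 ± 0.33) rose, and Os07g0576500 (-0.65 ± 0.06 and -0.65 ± 0.03) fell, the last by -0.44 in IR64 with median centring. Of 14 auxin response factor genes, 7 rose and 3 fell in IR64 and 9 rose and 3 fell in Dro1-NIL, the same when adjusted over the list alone. Factor 7 (Os02g0141100, 2.21 ± 0.31 and 2.25 ± 0.16) and factor 6 (Os02g0164900, 1.16 ± 0.06 and 1.32 ± 0.06) were higher and factor 16 (Os06g0685700, -0.82 ± 0.04 and -0.73 ± 0.03, and -0.43 and -0.32 with median centring) was lower. Of 10 lateral organ boundaries domain genes, regulators of lateral and crown root initiation, 5 rose in each variety, with 2 lower in IR64 and 4 in Dro1-NIL, the same when adjusted over the list alone. Examples are Os02g0820500 (2.86 ± 0.43 and 3.24 ± 0.27) and Os11g0106900 (3.17 ± 0.02 and 2.77 ± 0.15). None of these 3 lists was called by camera (adjusted p = 0.575, 0.189 and 0.431 in IR64, and 0.519, 0.113 and 0.519 in Dro1-NIL).

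SAUR genes, which are small auxin-up RNAs by name, mostly fell. Of 19 members, 11 fell and 4 rose in IR64 and 12 fell and 3 rose in Dro1-NIL (13 and 3 in Dro1-NIL when adjusted over the list alone), among them Os04g0608300 (-2.08 ± 0.15 and -2.36 ± 0.19) and Os09g0437400 (-1.55 ± 0.08 and -1.79 ± 0.12). The list was called lower in Dro1-NIL (median -0.70, camera adjusted p = 0.0359), where its adjusted p was 0.438 with an estimated correlation. In IR64 its adjusted p was 0.116 (median -0.58). With median centring the medians were -0.28 in IR64 and -0.49 in Dro1-NIL. The difference between the varieties' SAUR responses was not called (camera adjusted p = 0.067). With Feature Extraction's ratio it was called (camera adjusted p = 0.0498). Of 15 auxin transporter genes, 6 rose and 7 fell in IR64, and 7 rose and 5 fell in Dro1-NIL (7 and 6 when adjusted over the list alone). Os06g0232300 (1.82 ± 0.09 and 2.22 ± 0.25) was higher and Os08g0191000 (-1.37 ± 0.14 and -1.30 ± 0.06) lower. The transporters' median was -0.23 in IR64 and -0.12 in Dro1-NIL on the loess scale and 0.14 and 0.28 with median centring, while their mean was 0.14 and 0.35. The list was not called (camera direction lower in IR64 and higher in Dro1-NIL, adjusted p = 0.960 and 0.745).

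Glutathione S-transferases, enzymes of detoxification, were mostly higher. Of 59 measured genes, 40 rose and 5 fell in IR64, and 41 rose and 4 fell in Dro1-NIL (40 and 5, and 42 and 4, when adjusted over the list alone). GST 30 led them, followed by Os10g0528400 (3.75 ± 0.29 and 3.65 ± 0.12). The list's median was 0.59 and 0.70 (camera adjusted p = 2.75e-05 and 2.93e-05), and 0.93 in IR64 with Feature Extraction's values. With an estimated correlation the adjusted p was 0.309 and 0.323. Of 26 ethylene response factor genes, 15 rose and 5 fell in IR64 and 16 rose and 5 fell in Dro1-NIL, the same when adjusted over the list alone, such as Os02g0654700 (3.93 ± 0.21 and 3.63 ± 0.13). That list also holds translation release factor and methionine synthase genes, caught by their descriptions. It was called in Dro1-NIL (adjusted p = 0.0385, and 0.668 with an estimated correlation), not in IR64 (0.0756), and the difference between the varieties was not called (adjusted p = 0.888). Of 14 ethylene synthesis genes, 8 rose and 3 fell in each variety, the same when adjusted over the list alone, and the list was not called (adjusted p = 0.116 and 0.210). Members that rose were an ACC synthase (Os01g0192900, 3.09 ± 0.31 and 2.78 ± 0.13) and an ACC oxidase (Os11g0186900, 2.47 ± 0.12 and 2.49 ± 0.28).

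Histone and several cell wall lists were lower on the loess scale. Of 43 core histone genes, 39 fell in IR64 and 38 in Dro1-NIL, and 1 rose in each, with the same numbers when adjusted over the list alone. Examples are histone H3 (Os04g0419600, -2.76 ± 0.11 and -2.73 ± 0.05), H2B.1 (Os01g0152300, -2.38 ± 0.07 and -2.27 ± 0.05) and H2A (Os12g0530000, -2.31 ± 0.08 and -2.31 ± 0.06). The list's median was -1.50 and -1.58 (camera adjusted p = 9e-13 and 3.29e-12, and adjusted p = 0.588 and 0.668 with an estimated correlation). Of 11 xyloglucan endotransglucosylase genes, whose products remodel the primary wall, 10 fell in IR64 and 11 in Dro1-NIL, and the same numbers were found when adjusted over the list alone. Their median was -1.42 and -1.63 (adjusted p = 0.000809 and 0.000347, and adjusted p = 0.309 and 0.323 with an estimated correlation). Of 99 class III peroxidase genes, 55 fell and 22 rose in IR64 and 54 fell and 24 rose in Dro1-NIL, the same when adjusted over the list alone. Their medians were -0.62 and -0.47 (adjusted p = 0.013 and 0.0359, and adjusted p = 0.657 and 0.668 with an estimated correlation). Of 54 genes of xylem and secondary walls, markers of older root tissue, 28 fell and 8 rose in IR64 and 28 fell and 10 rose in Dro1-NIL (9 rose in Dro1-NIL when adjusted over the list alone). Among these, 4-coumarate-CoA ligase 1 (Os08g0245200, -2.17 ± 0.03 and -2.21 ± 0.06) and a gene described as cellulose synthase-7 (Os03g0837100, -2.01 ± 0.12 and -1.85 ± 0.04) fell. Members were matched by description, and whether this cellulose synthase acts in primary or secondary walls was not analysed here. The medians were -0.33 and -0.30 (adjusted p = 0.0126 and 0.0209, and adjusted p = 0.690 and 0.668 with an estimated correlation). With median centring the medians in IR64 and Dro1-NIL were nearer 0, at -0.09 and -0.15 for the xylem and secondary wall genes, -0.40 and -0.14 for the peroxidases, -1.06 and -1.03 for the histones and -1.19 and -1.21 for the xyloglucan endotransglucosylases.

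**Figure D1:**
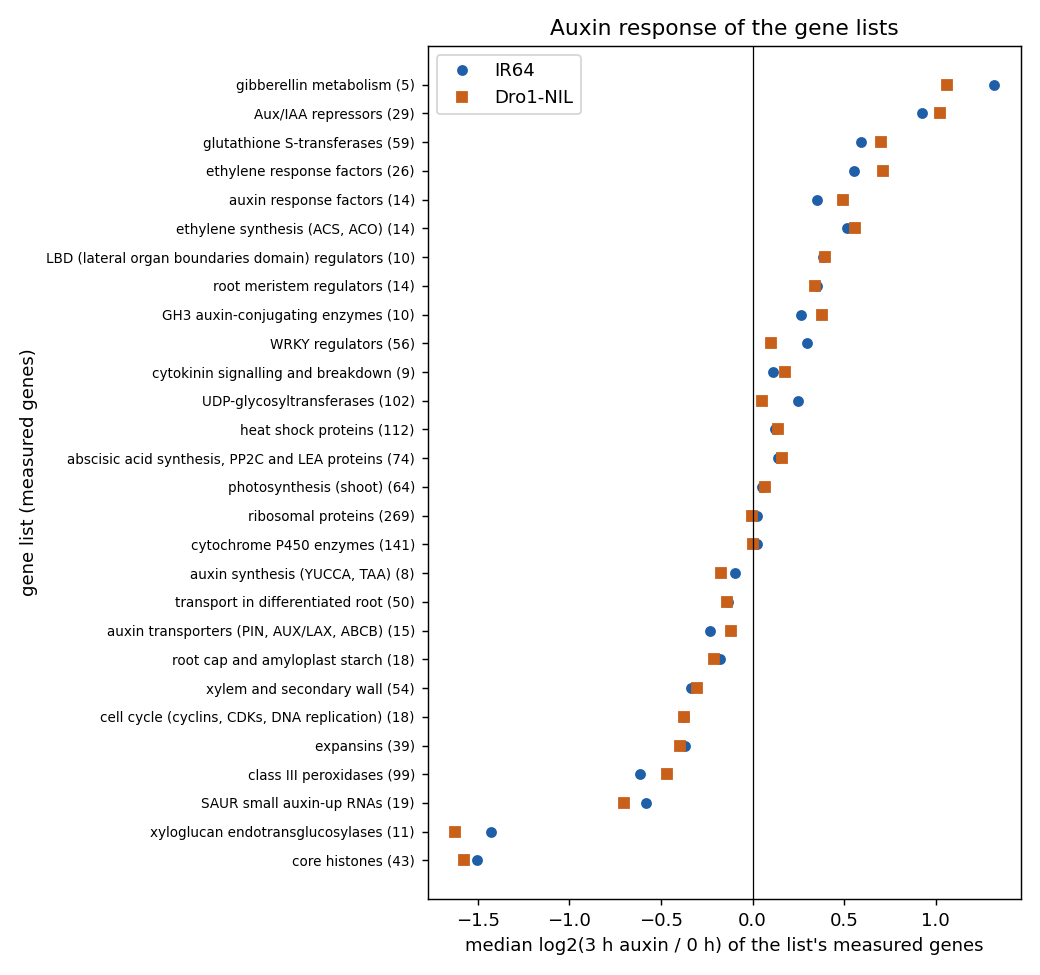
Median log2 ratio of 3 h auxin to 0 h over the measured genes of each tested gene list (number of measured genes in parentheses), with circles for IR64 and squares for Dro1-NIL (each point from 3 arrays). Aux/IAA genes lie at 0.92 and 1.02 and core histones at -1.50 and -1.58, while the medians of auxin transporters, auxin synthesis, root cap, differentiated-root transport, expansin (IR64) and ribosomal protein (Dro1-NIL) genes turn from negative to positive with median centring.

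None of the remaining lists was called in either variety. Among growth and cell wall lists, 22 of 39 expansin genes fell and 11 rose in each variety (23 fell in IR64 when adjusted over the list alone), with medians of -0.37 and -0.40 (adjusted p = 0.116 and 0.0804); with median centring the medians were 0.01 and -0.08. Of 18 cell cycle genes, 10 fell and 6 rose in each variety, and of 14 root meristem regulators 8 rose and 4 fell in each, the same when adjusted over the list alone. Of 269 ribosomal protein genes, 87 rose and 58 fell in IR64 (77 and 50 when adjusted over the list alone), and 72 rose and 64 fell in Dro1-NIL (68 and 55). Their Dro1-NIL median was -0.00347 against a mean of 0.0158, a camera direction of higher, and medians of 0.47 with median centring and -0.03 with Feature Extraction's values. Of 18 root cap and amyloplast genes, 5 rose and 9 fell in IR64 and 5 rose and 7 fell in Dro1-NIL, the same when adjusted over the list alone, with medians of -0.18 and -0.21 that became 0.13 and 0.17 with median centring. Of 50 transport genes of differentiated root, 16 rose and 25 fell in IR64 and 18 rose and 23 fell in Dro1-NIL (24 fell when adjusted over the list alone), with medians of -0.14 in each that became 0.14 and 0.12 with median centring. Of 64 photosynthesis genes, 23 rose and 15 fell in IR64 and 25 rose and 18 fell in Dro1-NIL, the same when adjusted over the list alone. That list was led by plastocyanin-like domain proteins, and its Dro1-NIL median of 0.07, with a camera direction of higher, stood against a mean of -0.00868 and became 0.15 with median centring. Of 2 measured root hair genes, too few for a list test, none was called by limma over all genes or when adjusted over the list alone.

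Among hormone and stress lists, 3 of 8 auxin synthesis genes rose and 3 fell in IR64 and 2 rose and 3 fell in Dro1-NIL, the same when adjusted over the list alone, with medians of -0.09 and -0.17 that became 0.19 and 0.16 with median centring. Of 9 cytokinin genes, 4 rose and 3 fell in each variety, the same when adjusted over the list alone; their medians of 0.11 and 0.18, with a camera direction of higher, stood against means of -0.03 and -0.05, and with median centring the medians were 0.49 and 0.59. Of 5 gibberellin metabolism genes, 3 rose in each variety, the same when adjusted over the list alone, with medians of 1.32 and 1.06 (adjusted p = 0.116 and 0.151) that became 2.04 and 1.95 with Feature Extraction's values. Of 74 genes of abscisic acid synthesis, PP2C phosphatases and LEA proteins, 34 rose and 21 fell in IR64 (35 and 21 when adjusted over the list alone) and 37 rose and 20 fell in Dro1-NIL (37 and 20). Of 141 cytochrome P450 genes, 48 rose and 45 fell in IR64 (47 and 45 when adjusted over the list alone) and 50 rose and 53 fell in Dro1-NIL (51 and 54). Of 102 UDP-glycosyltransferase genes, 47 rose and 42 fell in IR64 (47 and 42 when adjusted over the list alone) and 47 rose and 41 fell in Dro1-NIL (47 and 42). Of 112 heat shock protein genes, 49 rose and 36 fell in IR64 (50 and 36 when adjusted over the list alone) and 57 rose and 34 fell in Dro1-NIL (59 and 34). Of 56 WRKY regulators, 28 rose and 15 fell in IR64 and 26 rose and 16 fell in Dro1-NIL, the same when adjusted over the list alone.

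The responses of the varieties were close across genes. In all, 14251 genes were called in the same direction in both, 7223 higher and 7028 lower, and 34 were called in opposite directions. Independent lists of these sizes would share 2977 higher and 2725 lower genes. The mean responses correlated at r = 0.971 across genes, which are not independent replicates, with a slope of 1.01 for Dro1-NIL on IR64 and a median size of the difference of 0.09. The varieties shared no array, but they shared the dye orientation, and a common dye bias would add to this overlap. Both sets of calls also used 1 shared estimate of each gene's spread, which favours joint calls over those of independent lists.

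**Figure D2:**
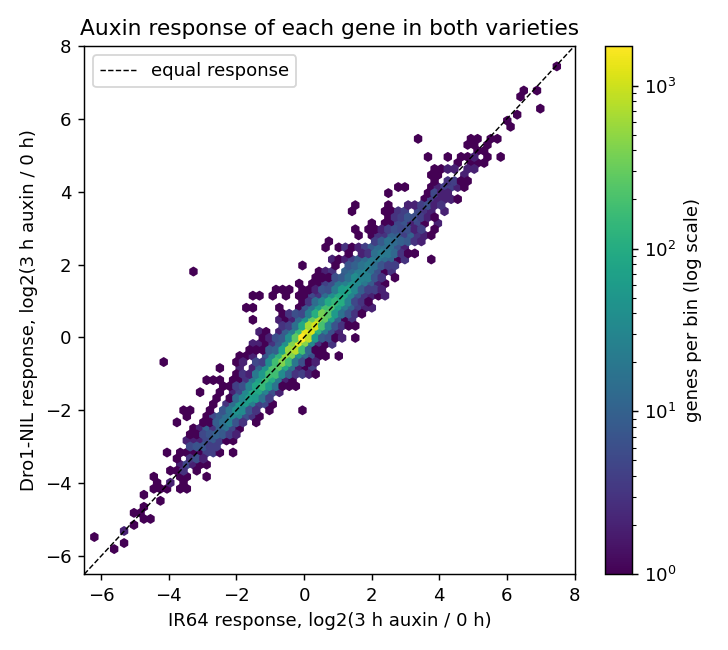
Log2 ratio of 3 h auxin to 0 h of each of the 21911 genes in IR64 (x axis) and Dro1-NIL (y axis), coloured by the number of genes per bin on a log scale; the dashed line marks equal responses. Points follow that line, with a slope of 1.01.

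DRO1 (Os09g0439800), the gene at which the lines were made to differ, fell in both varieties. Its single probe gave log2 ratios of -1.31 ± 0.10 in IR64 and -1.66 ± 0.13 in Dro1-NIL (SD, n = 3 each; limma adjusted p = 7.24e-06 and 2.8e-06), lower at 3 h on all 6 arrays. Of the related genes of root gravitropism, qSOR1 (Os07g0614400, -0.36 ± 0.06 and -0.43 ± 0.10, and -0.65 and -0.83 with Feature Extraction's values) fell. LAZY1 (Os11g0490600) was not well above background at 0 h in IR64 and was at least 1.17-fold higher at 3 h (limma adjusted p = 0.0148), a call that ended without IR64 replicate 3 (adjusted p = 0.0784) and with median centring (0.911). In Dro1-NIL it rose by 0.58 ± 0.11 (1.72 with Feature Extraction's values), and the difference between its responses was not called (adjusted p = 0.210). These 3 genes form the gravitropism list, in which 1 rose and 2 fell in each variety, the same when adjusted over the list alone.

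Between the varieties, DRO1 differed by -0.01 at 0 h (adjusted p = 0.97) and by -0.36 at 3 h (Dro1-NIL minus IR64, adjusted p = 0.0577). Its responses differed by -0.35 (adjusted p = 0.237; -0.11, -0.54 and -0.39 within the 3 slides), so none of these 3 contrasts was called. With the slide as a fixed block the adjusted p at 3 h was 0.0397 (0.0188 as a random term), and without IR64 replicate 1 it was 0.0415. The place of the probe relative to the allele difference was not analysed here.

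**Figure D3:**
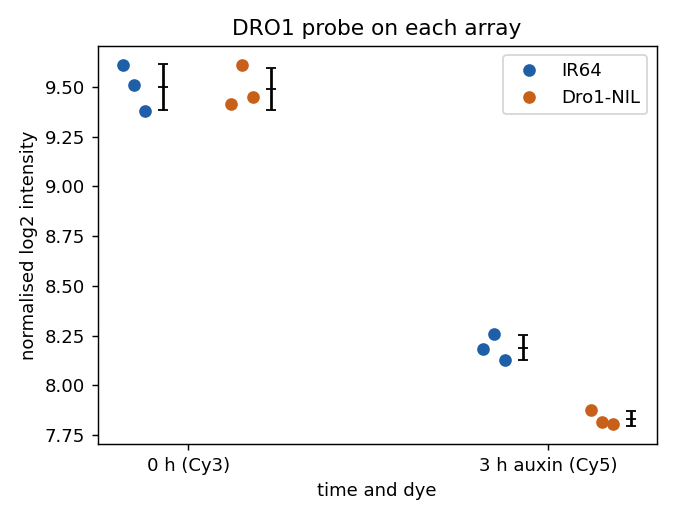
Normalised log2 intensity of the DRO1 probe on each array at 0 h (Cy3) and after 3 h of auxin (Cy5), with a point per array (3 per variety) and the mean ± SD beside them. The values of the varieties overlap at 0 h, while at 3 h the Dro1-NIL arrays lie below the IR64 arrays by 0.36 on average, a difference that was not called; the dyes differ between the times.

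The comparison the series was built for asks whether the auxin response itself differs between the varieties. The genes of smallest p were a clathrin adaptor gene (Os09g0449500), at -0.46 ± 0.11 in IR64 and 1.14 ± 0.20 in Dro1-NIL, and a UDP-glycosyltransferase gene (Os09g0482900), at 0.21 ± 0.12 and -0.91 ± 0.08. Next were FKF1 (Os11g0547000, -0.47 ± 0.08 and 0.37 ± 0.04), a blue-light receptor, and an aspartic peptidase gene (Os01g0937600, 0.77 ± 0.09 and -0.25 ± 0.13). Thioredoxin-like 1 (Os07g0684100, 2.06 ± 0.09 and 1.22 ± 0.11) and a squalene/phytoene synthase gene (Os12g0626400, -0.38 ± 0.09 and -1.23 ± 0.12) followed. None of the 6 passed the threshold (limma adjusted p = 0.0701 each, the smallest over all genes). Without IR64 replicate 1 all 6 passed, with adjusted p of 0.0311 to 0.0488, as they did with array weights (0.00413 to 0.00925). With median centring Os09g0449500 (difference 1.95, adjusted p = 0.0320) and Os09g0482900 (-1.12, 0.0394) passed, and with Feature Extraction's values the difference of Os09g0449500 was 2.80 and did not pass (0.0782).

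Of the 21911 tested genes, 2850 had an unadjusted limma p under 0.05 for this difference. Without any difference, a share of 0.05 of the genes would be met by chance. After adjustment limma called 0 genes, which does not show that the responses are equal. The count was 0 with the slide as a fixed or random block as well, 3 with median centring, 44 without IR64 replicate 1, 1 without Dro1-NIL replicate 3 and 2335 with array weights. Those weights were 0.20 for IR64 replicate 1 and 4.41 for IR64 replicate 2. Among the gene lists, the 15 auxin transporter genes responded higher in Dro1-NIL by a median of 0.13 (camera adjusted p = 0.0385, and 0.0115 with the slide as a fixed block; within the 3 slides 0.14, 0.44 and 0.16). With an estimated correlation the adjusted p was 0.963, and no single member was called over all genes or when adjusted over the list alone. The transporter call ended without IR64 replicate 2 (adjusted p = 0.0917), IR64 replicate 3 (0.199) or Dro1-NIL replicate 1 (0.0689). The number of lists called was 3 without IR64 replicate 1, 0 without IR64 replicate 2, IR64 replicate 3 or Dro1-NIL replicate 1, 2 without Dro1-NIL replicate 2 and 4 without Dro1-NIL replicate 3.

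Before treatment, the genes that differed between the varieties lay mainly on chromosome 9, where DRO1 is. A trypsin-like peptidase gene (Os09g0436300), a cellulose synthase family gene (Os09g0478100) and an esterase/lipase gene (Os09g0460700) were not well above background in IR64 and were at least 10.8-fold, at least 6.24-fold and at least 2.90-fold higher in Dro1-NIL. Aconitase of the citric acid cycle (Os09g0449600, 1.36 ± 0.09 SE), a prolyl oligopeptidase gene (Os09g0475700, 1.29 ± 0.09 SE), an RNA-binding protein gene (Os09g0476100, 1.11 ± 0.08 SE) and ketol-acid reductoisomerase of branched-chain amino acid synthesis (Os09g0436500, 1.04 ± 0.06 SE) were also higher. A family 1 glycoside hydrolase (Os09g0490400, -3.11 ± 0.06 SE) was lower, and these 8 genes kept their call and direction under every alternative that tested them. The strict filter left out probes not above background on every array and dye, and array weights were used for the difference in response only. Sizes moved with Feature Extraction's values for Os09g0475700 (2.25) and with the mean of all probes for Os09g0476100 (0.56) and Os09g0436500 (2.93).

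The other 8 named genes at 0 h were less stable. A jumonji-domain gene (Os09g0483600, -1.17 ± 0.10 SE) and caffeoyl-CoA O-methyltransferase of lignin synthesis (Os09g0481400, -0.96 ± 0.07 SE) were lower in Dro1-NIL, and with the slide as a fixed block their adjusted p was 0.0787 and 0.0619. A beta-1,3-glucanase homologue (Os09g0502200) was lower by its brightest probe (-0.89 ± 0.07 SE) and higher by the mean of its probes (0.88). Outside chromosome 9, a family 16 glycoside hydrolase (Os08g0240500, -1.14 ± 0.12 SE) was lower, a call that ended without IR64 replicate 3 (adjusted p = 0.0632) and without Dro1-NIL replicate 3 (0.0704), and with Feature Extraction's values its difference was -1.93. A cyclin-dependent kinase inhibitor gene (Os09g0459900, 1.07 ± 0.13 SE), a lipolytic enzyme gene (Os01g0223200, -0.93 ± 0.11 SE), a photosystem I subunit gene (Os09g0481200, -0.93 ± 0.10 SE) and an expansin-related gene (Os09g0472900, not well above background in Dro1-NIL and at least 1.82-fold lower) each lost the call with the slide as a fixed block (adjusted p = 0.138 to 0.186). These 6 calls held with the slide as a random term. The call of the lipolytic enzyme gene also ended without any 1 of the 6 arrays, and that of the expansin-related gene without any but IR64 replicate 2. The call of the kinase inhibitor gene ended without IR64 replicate 1, 2 or 3 or Dro1-NIL replicate 3, and that of the photosystem gene without IR64 replicate 2 or 3 or Dro1-NIL replicate 2 or 3 (adjusted p of the 4 genes without these arrays 0.0553 to 0.135).

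At 0 h limma called 88 genes, 53 higher and 35 lower in Dro1-NIL, and 59 of them (36 higher and 23 lower) were among the 1172 tested genes of chromosome 9. These 59 lay between the loci Os09g0432900 and Os09g0506200, a span that holds 308 tested genes and, by locus number, DRO1. With the slide as a fixed block 27 genes were called, 20 of them on chromosome 9, and as a random term 76 (47 higher and 29 lower), 53 of them on chromosome 9. All 27 and all 76 were among the 88. Of the 88 genes, 87 had the same direction on all 3 slides, which their selection from these values favours. With both channels in 1 fit 366 genes were called, of which 148 were higher and 218 lower. The count was 40 without IR64 replicate 2, 52 without IR64 replicate 3, 51 without Dro1-NIL replicate 1, 43 without Dro1-NIL replicate 2 and 40 without Dro1-NIL replicate 3.

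**Figure D4:**
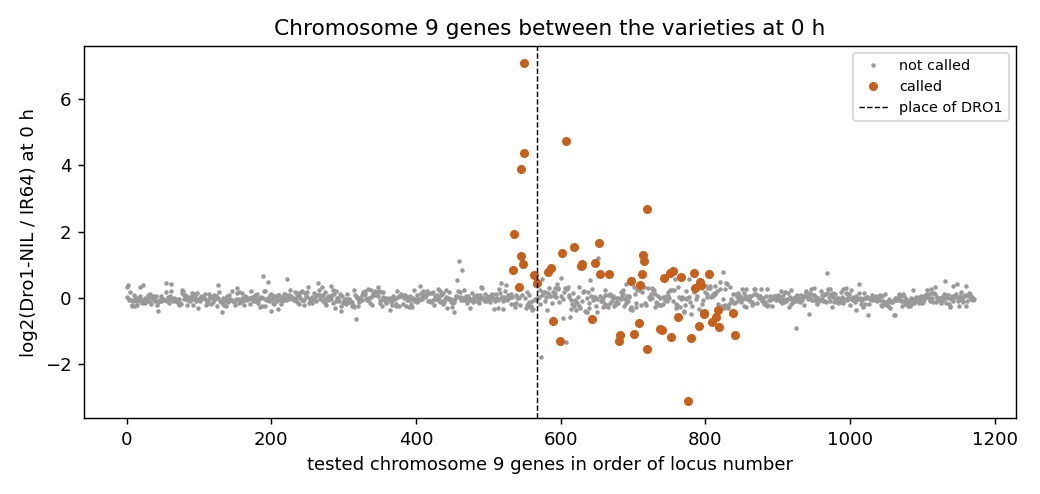
Difference between Dro1-NIL and IR64 at 0 h (log2, y axis) for the 1172 tested genes of chromosome 9 in order of locus number (x axis), with larger points for the 59 called genes and a dashed line at the place of DRO1. The called genes lie in 1 stretch of 308 tested genes.

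Small shifts of gene lists were also found at 0 h. In Dro1-NIL, 269 ribosomal protein genes were lower by a median of -0.09 (camera adjusted p = 1.87e-09; within slides -0.17, -0.05 and -0.05) and 43 core histone genes by -0.12 (2.71e-05; -0.20, -0.00115 and -0.19). WRKY regulators were higher by 0.08 (adjusted p = 0.000303; 0.13, 0.09 and 0.02) and SAUR genes by 0.13 (0.039; 0.05, 0.05 and 0.01). Transport genes of differentiated root were higher by 0.07 (adjusted p = 0.00244; 0.22, 0.02 and -0.03) and cytochrome P450 genes by 0.04 (0.0394; 0.13, 0.00424 and -0.00691), so both lost their direction within slide 3. With an estimated correlation the adjusted p was 0.525 for each of these 6 lists. Of their members, 2 ribosomal protein genes were called lower and 1 P450 gene higher over all genes; adjusted over the list alone, 6 WRKY and 3 transport genes were higher as well. The SAUR call ended without IR64 replicate 3 (adjusted p = 0.0823), Dro1-NIL replicate 1 (0.0626) or Dro1-NIL replicate 2 (0.0823), the P450 call without IR64 replicate 1 (0.281) or Dro1-NIL replicate 1 (0.0807) and the transport call without IR64 replicate 1 (0.205). With the slide as a fixed block, GH3 genes (0.09, adjusted p = 0.0324) and the list of abscisic acid, PP2C and LEA genes (0.04, 0.0336) were called too. Without the block both missed the threshold (camera adjusted p = 0.0608 each), and no list was called at 0 h with an estimated correlation.

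After 3 h of auxin, the differences between the varieties again included genes of chromosome 9. The trypsin-like peptidase gene Os09g0436300 was at least 13.2-fold higher in Dro1-NIL, and the cellulose synthase family gene Os09g0478100 (2.89 ± 0.12 SE) and the clathrin adaptor gene Os09g0449500 (2.19 ± 0.10 SE) were higher. The glycoside hydrolase Os09g0490400 (-4.26 ± 0.11 SE), the UDP-glycosyltransferase Os09g0482900 (-1.12 ± 0.06 SE), caffeoyl-CoA O-methyltransferase (Os09g0481400, -0.90 ± 0.07 SE) and the jumonji-domain gene Os09g0483600 (-0.87 ± 0.07 SE) were lower. These 7 genes kept their call and direction under every alternative that tested them, while with Feature Extraction's values Os09g0478100 differed by 4.47 and Os09g0449500 by 3.68.

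The other 9 named genes at 3 h were less stable. A transposon protein gene (Os07g0431000, 4.24 ± 0.60 SE), a cationic peroxidase (Os07g0677600, 2.55 ± 0.24 SE), an esterase/lipase gene (Os09g0460400, 1.49 ± 0.19 SE), a NifU-domain gene (Os09g0481800, 1.48 ± 0.15 SE) and a MatE-family efflux gene (Os03g0858800, 1.45 ± 0.23 SE) were higher in Dro1-NIL. The ethylene synthesis gene ACC oxidase 1 (Os09g0451000, -2.92 ± 0.35 SE), pathogenesis-related protein PRB1-2 (Os01g0382400, -1.17 ± 0.12 SE), an RCc2 root-specific protein (Os10g0552300, -0.94 ± 0.14 SE) and a LysM-domain gene (Os09g0452200, -0.89 ± 0.12 SE) were lower. Each of these 9 calls ended without IR64 replicate 2, without IR64 replicate 3 and without Dro1-NIL replicate 2 (adjusted p = 0.0612 to 0.2295). All but those of Os07g0431000 and Os07g0677600 ended without Dro1-NIL replicate 1 as well (0.0751 to 0.167), and that of Os10g0552300 also without Dro1-NIL replicate 3 (0.0568). The call of Os09g0452200 ended with the mean of its probes (-0.57, adjusted p = 0.0527) and that of Os07g0677600 with both channels in 1 fit (0.0790). Those of Os07g0431000, Os03g0858800 and Os10g0552300 ended with no filter on dim probes (0.0501, 0.0676 and 0.0591), those of Os03g0858800 and Os10g0552300 without a variance trend (0.0574 and 0.0536) and that of Os03g0858800 with the strict filter (0.0502). Sizes moved with Feature Extraction's values for Os07g0431000 (6.43), Os07g0677600 (4.84) and Os01g0382400 (-2.26), and with the mean of its probes for Os09g0460400 (0.99).

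At 3 h limma called 221 genes, 78 higher and 143 lower in Dro1-NIL, of which 82 lay on chromosome 9. Of these 82, 75 lay in the stretch found at 0 h, 1 before it and 6 after it. With the slide as a fixed block 2099 genes were called (1072 higher and 1027 lower) and as a random term 2672 (1004 higher and 1668 lower), and each set held all 221. Of the 221, 219 had the same direction on all 3 slides, which their selection favours. The count was 1942 without IR64 replicate 1 (1086 higher), 39 without IR64 replicate 2 (23 higher), 47 without IR64 replicate 3 (29 higher), 48 without Dro1-NIL replicate 1 (28 higher), 39 without Dro1-NIL replicate 2 (23 higher) and 245 without Dro1-NIL replicate 3 (116 higher). The larger number of lower calls therefore turned with the fixed block and without any 1 of 5 arrays, but not with the random term. Called at both times were 54 genes, each in the same direction, 44 of them on chromosome 9; the values of the times come from both dyes of the same spots and are not independent.

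Ribosomal protein genes were lower in Dro1-NIL at 3 h by a median of -0.11 (camera adjusted p = 5.67e-15; within slides -0.12, -0.14 and -0.08), with 5 members lower and 1 higher over all genes and 83 lower and 1 higher when adjusted over the list alone. Core histones (-0.13, adjusted p = 0.0032) and expansins (-0.18, 0.0193) were lower too. Of the histones, 10 were lower when adjusted over the list alone; of the expansins, 1 was lower over all genes, and 7 were lower and 1 higher when adjusted over the list alone. Higher were auxin response factors (0.10, adjusted p = 0.012), auxin transporters (0.20, 0.0291), GH3 genes (0.12, 0.037), root meristem regulators (0.07, 0.0139), transport genes of differentiated root (0.06, 0.00145) and the abscisic acid, PP2C and LEA genes (0.04, 0.0193). Of these 6 lists, 1 response factor and 1 meristem regulator were higher when adjusted over the list alone. The GH3 call ended without IR64 replicate 3 (adjusted p = 0.102) or Dro1-NIL replicate 1 (0.0503), the transporter call without the same arrays (0.0881 and 0.0780) and the expansin call without IR64 replicate 2 (0.0527). All 9 shifts had the same direction within each slide, which their selection from these values favours. Of all tested genes, 57.4% had the same direction on all 3 slides at 3 h, and the median over all genes was -0.03. With an estimated correlation the camera adjusted p was 0.602 for each list.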

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

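The tests of nitrate supply, low oxygen and time of day, the list values without 1 array, and the restriction of the second-probe tests to probes without 20 shared bases, were chosen only after the results were seen; the other tests in this part were written before them. Each of 5 named genes had the 3 arrays of one variety above 0 and the 3 of the other below 0 and missed the threshold in the test of the difference, with a limma adjusted p of 0.0701 each. These were the clathrin adaptor gene Os09g0449500 (difference 1.60), the UDP-glycosyltransferase Os09g0482900 (-1.12), FKF1 Os11g0547000 (0.84), the aspartic peptidase Os01g0937600 (-1.02) and the glycoside hydrolase Os09g0490400 (-1.15). A root hair defective 3 gene (Os01g0575000) showed the same split at a difference of 0.0506 (limma adjusted p = 0.656). With median centring its mean was above 0 in both varieties (0.41 in IR64 and 0.46 in Dro1-NIL), so its split rests on the loess scale. In all, 183 of 21911 genes (0.835%) had the varieties' arrays on opposite sides on that scale. The share that chance would give was not computed, so this count is not evidence of a difference. The auxin transporter list responded higher in Dro1-NIL by a median of 0.13 (camera adjusted p = 0.0385), a call that ended without IR64 replicate 2 (0.0917), IR64 replicate 3 (0.199) or Dro1-NIL replicate 1 (0.0689). With an estimated correlation its adjusted p was 0.963.

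The first pattern weighed is the set of 88 genes that differed at 0 h, in which the share of chromosome 9 was 12.5 times its share among tested genes (Fisher's exact test, two-sided, p = 1.05e-53), which is consistent with a segment of Kinandang Patong DNA around DRO1. Sequence mismatches to the probes could lower the signal without a change in expression. Of 19 called genes of chromosome 9 with a second tested probe, 8 had one that shared 20 or more bases with the first and would share a mismatch. Over the other 11 the second probe's difference was 0.592 of the first's (bootstrap SD 0.387, 8 on the same side), which leaves mismatches open, and the bound set for excluding them (met over all 19, at 0.895 ± 0.162) was wrong because of those shared bases. A better match of the introgressed allele to the array would raise most genes in Dro1-NIL, and 61.0% of the called genes of chromosome 9 were higher, which decides neither way.

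The second pattern is the size of the auxin response, called for 17448 genes over both varieties. Of 32 assignments of signs to the 6 log ratios, 1, the real one, gave as many calls and the highest of the others gave 0. This argues against chance signs, at the smallest share that 32 assignments allow. Since the arrays correlated at 0.90 to 0.976, turning the signs of any of them widens the spread of most genes. The test therefore shows no more than that the arrays share their directions. Dye bias set by the base composition of the probe is argued against, since base counts explained 0.0213% of the variance of the response. Dye bias set by single probes is argued against for calls under 2-fold, since over 1935 genes the response of a second probe without 20 shared bases correlated with that of the first at 0.844 across genes (0.922 over all 4044). A bias shared by all probes of a transcript, transfer to fresh solution and elapsed time were not tested, and without a dye swap or untreated tips at 3 h they may contribute to these calls.

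The next pattern is the place of some nitrogen and hemoglobin genes among the highest responses, which might come from a different nitrate supply, from low oxygen or from the time of day. Over 31 other nitrate-related genes, 7 of them also in the fixed lists and 1 an oxygen-evolving protein caught by its description, the median response was 0.42 (bootstrap SD 0.57) with 61.3% higher, between the values set for either outcome. Over 24 low-oxygen genes it was 0.37 ± 0.17 (bootstrap SD), below the 1 that low oxygen would need but not low enough to exclude it by the bound set. Over 4 circadian clock genes the median size of the response was 1.62 ± 0.62 (bootstrap SD) against 0.35 for all genes, as the time of day would need. Of these 4, 3 were called higher and 0 lower. FKF1 had already been seen, and it moved in opposite directions in IR64 (-0.47) and Dro1-NIL (0.37). A direct effect of auxin on such genes stays open. The test does not link the nitrogen and hemoglobin genes themselves to the time of day, so it cannot decide their cause.

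Other splits of the arrays bear on the remaining counts, and each is too few for a share under 0.05. Of the 10 splits of the 6 arrays, 1, the real one, gave as many as 88 genes at 0 h and 1 gave as many as 221 at 3 h, where the highest of the others gave 0 each. For the difference in response the real count was 0 and the highest other 0, so that 10 of 10 splits gave as many. A real count of 0 fixes this outcome in advance, so the splits cannot decide anything about the difference. Of 4 assignments of signs within a variety, 1 gave as many as 15638 genes in IR64 and 1 as many as 15969 in Dro1-NIL, where the highest other gave 0 each.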

How the results depend on the processing

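The variance trend as first run, the left-out arrays for lists, overlap and DRO1, the other settings of DRO1 except Feature Extraction's values and the fixed block, and the slide block and median centring for lists were chosen only after the data were seen. Same-numbered arrays share a slide, but their deviations did not pair on every slide (correlations of -0.12, -0.48 and 0.47 for ratios, -0.18, -0.17 and 0.10 for Cy3 and 0.38, -0.20 and 0.54 for Cy5, not all over 0.1 in any). For Cy5 they paired on slides 1 and 3 (0.38 and 0.54) and not on slide 2 (-0.20), so a slide effect at 3 h stays open. The replicate block gave 27 genes as a fixed and 76 as a random term at 0 h, and 2099 and 2672 at 3 h. At 0 h the count was 47 with the strict filter on dim probes (fewer genes tested), 366 with both channels in 1 fit and 40 to 63 without 1 array. At 3 h it was 139 with no filter, 778 with both channels in 1 fit and 39 to 1942 without 1 array. For the difference in response it was 3 with median centring, 3 with the variance trend as first run, 2335 with array weights and 0 to 44 without 1 array. Chromosome 9 calls were 59 at 0 h (20 with the fixed and 53 with the random block, 35 with the strict filter, 102 with both channels, 29 to 46 without 1 array) and 82 at 3 h (199 with the fixed and 246 with the random block, 142 with both channels, 29 to 190 without 1 array). DRO1 crossed the threshold at 3 h with the replicate block fixed or random (-0.36 each; adjusted p = 0.0397 and 0.0188), with Feature Extraction's values (-0.50, 0.0491), with both channels in 1 fit (-0.36, 0.0319) and without IR64 replicate 1 (-0.36, 0.0415; range without 1 array -0.39 to -0.32). Its difference in response crossed with array weights (-0.38, 0.0306; range without 1 array -0.41 to -0.28). List calls numbered 6 in IR64 (0 with an estimated correlation, 21 by fry), 8 in Dro1-NIL (0 and 22), 1 for the difference (0 and 0, 5 with Feature Extraction's ratio, 0 to 4 without 1 array), 6 at 0 h (0 and 0) and 9 at 3 h (0 and 1). The fixed replicate block moved no list count by over 1.5 times. Directions turned with median centring for Os01g0575000 (0.41 in IR64), Os01g0927600 (0.13 in IR64 and 0.15 in Dro1-NIL) and Os01g0231000 (0.28 and 0.40), and for Os09g0502200 at 0 h (0.88) with the mean of its probes. Calls of the auxin response stayed within 13886 to 15828 genes in IR64 and 13790 to 17166 in Dro1-NIL without 1 array, and the overlap within 12861 to 14486. Of 129 named genes, 121 in IR64 and 123 in Dro1-NIL kept their direction and side of the threshold under every alternative that tested them, as did 8 of 16 at 0 h, 7 of 16 at 3 h and 0 of 6 for the difference. Apart from the strict filter, the cause was not tested. Signal over background limits the rest of the probes beyond the 70.2% to 75.6% that were well above it.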

Other observations

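The grouping of the genes in this paragraph was chosen after their values were seen. Some genes of nitrate assimilation rose in both varieties. In IR64 and Dro1-NIL, the second nitrite reductase (Os02g0765900) rose by 5.33 ± 0.07 and 5.31 ± 0.04 (SD, n = 3 each), uroporphyrinogen III methyltransferase (Os01g0631200), which acts in making the siroheme of that enzyme, by 5.29 ± 0.08 and 5.19 ± 0.16. Of the other uroporphyrinogen genes, the decarboxylases Os01g0622300 (-0.97 ± 0.13 and -0.91 ± 0.10) and Os03g0337600 (-0.78 ± 0.13 and -0.75 ± 0.10) fell, and the synthase Os03g0186100 was not called (0.04 ± 0.08 and -0.02 ± 0.06). The nitrate reductases rose as well, Os02g0770800 by 4.18 ± 0.15 and 4.23 ± 0.13, Os08g0468100 by 2.83 ± 0.13 and 2.71 ± 0.21 and Os08g0468700 by 2.17 ± 0.10 and 2.09 ± 0.14. Asparagine synthetase (Os03g0291500) rose by 4.83 ± 0.28 and 5.02 ± 0.31 (the second such gene, Os06g0265000, by 0.33 in each), hemoglobin gene Os05g0517600 by 4.22 ± 0.29 and 4.19 ± 0.21 and hemoglobin 3 (Os03g0234000) by 2.01 ± 0.20 and 2.05 ± 0.18. Hemoglobin 4 (Os03g0234100) was not called (-0.87 ± 1.17 and -0.04 ± 0.63; limma adjusted p = 0.208 for the mean of both), and the 2-on-2 hemoglobin (Os06g0591600) fell (-0.46 ± 0.05 and -0.54 ± 0.02). Over the list of 31 nitrate-related genes other than the first seen, which includes the nitrate reductases above, 19 were higher and 7 lower. Among the higher were the glutamine synthetases Os03g0712800 (3.53 in IR64 and 3.70 in Dro1-NIL), Os04g0659100 (2.86 and 3.09) and Os03g0223400 (2.47 and 2.97). A ferredoxin-NADP reductase (Os03g0784700, 3.90 and 4.02) and the glutamate synthases Os01g0681900 (2.94 and 3.08) and Os07g0658400 (1.72 and 1.82) rose too. So did the nitrate transporter Os10g0554200 (0.72 and 0.80). A glutamate synthase (Os05g0555600, -1.03 ± 0.29 and -1.20 ± 0.24) and the nitrate transporters Os03g0687000 (-0.76 ± 0.14 and -0.85 ± 0.06), Os10g0111700 (-0.68 ± 0.43 and -0.74 ± 0.22) and Os03g0235900 (-0.51 ± 0.47 and -0.56 ± 0.17) fell, and a glutamine synthetase (Os02g0735200, -0.03 ± 0.19 and -0.04 ± 0.07) was not called.

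Several groups that were not called as lists held single genes with high responses in both varieties. The gibberellin-inactivating enzyme gene Os05g0560900 rose by 3.32 ± 0.24 and 3.50 ± 0.15 and the small heat shock protein gene Os03g0267000 by 4.51 ± 0.18 and 4.36 ± 0.07. WRKY transcription factor 71 (Os02g0181300) rose by 4.09 ± 0.25 and 3.53 ± 0.06 and the P450 gene Os06g0294600 by 3.71 ± 0.03 and 3.52 ± 0.12. Alpha-expansin 19 (Os03g0428700, -3.41 ± 0.10 and -3.45 ± 0.12) fell, and expansin S1 (Os03g0336400) rose by 3.07 ± 0.06 and 2.72 ± 0.19. A root cap family gene (Os04g0410400, -1.99 ± 0.20 and -2.14 ± 0.11) fell, and 2 AINTEGUMENTA-type meristem genes, Os02g0614300 (-0.95 ± 0.08 and -0.81 ± 0.04) and Os01g0899800 (-0.86 ± 0.04 and -0.71 ± 0.04), were lower, by -0.56 and -0.40 and by -0.55 and -0.40 with median centring.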
